A study of Mus musculus with 12 samples.

How the data were processed

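Gene expression was measured in mouse myocardium with single-colour Affymetrix arrays on 12 samples, 4 in each of 3 groups. The groups were negative control mice injected with vehicle (NC), mice made diabetic with streptozotocin (DM), a toxin that destroys the insulin-producing beta cells of the pancreas, and diabetic mice that also received angiotensin IV (AngIV), a short peptide cleaved from angiotensin II. Per the labels' protocols, injections were given for 5 days, diabetic mice entered the experiment with a fasting glucose of at least 16.7 mM measured 2 weeks later, and angiotensin IV was infused at 2.88 mg/kg/day from week 8 to week 24. The labels give an age or time of 6 months for the tissue. Total RNA was extracted with Trizol and 6 micrograms of it were turned into biotin-labelled cRNA, per the labels' protocols.

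Groups were taken from the sample titles, which match the source names and the series design. The disease state tag goes against them: it calls the 4 NC samples diabetic and the 4 AngIV samples negative controls, and it was not used. The design describes 4 mice in each group, so each array was treated as 1 mouse. Titles number the replicates 1 to 4 in every group, and no label says that a number marks a shared litter, cage or day.

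The authors deposited 1 table of log2 signals per probe set, made with RMA (robust multi-array average: background correction, quantile normalization between arrays and a summary over the probes of a probe set), per the submitters' processing notes; the log2 scale was read from the range of the values. The version of RMA, the chip description file and the genome build were not given in the sources used here. Quantile normalization gives every array nearly the same distribution of values, so a change in the total amount of mRNA per sample cannot be seen in these values, and RMA summaries compress large differences and differences near background.

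The table held 29129 probe sets. Of these, 6923 were control probe sets and were left out of the tests. Of the 22206 transcript probe sets, 19572 were given 1 gene symbol by the platform annotation, 2634 were given none and 0 were given several. All 19572 were matched by Entrez ID to a RefSeq gene table of the GRCm38 assembly, and the update changed 0 symbols. The 19572 probe sets named 19505 genes, and for the 55 genes with over 1 probe set the one with the highest mean signal over all 12 arrays was kept. The dimmest 30% of genes, those with a mean log2 signal under 3.40, were left out, which left 13653 genes. No coordinates are given, since the build behind the probe sets was not given.

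Signal over background limits what arrays can resolve. The control probe sets gave a measure of it on each array: the chance that a positive control probe set was brighter than a negative one was 0.913 to 0.930 over the 12 arrays. The 95th percentile of the negative ones lay between 5.39 and 5.60, and a gene whose mean in a compared group was below it is given no ratio in the text. Where a log2 change of such a gene is printed, it is a difference of signals near background, whose size is not a measured fold of RNA, and the gene is named as such under its comparison. This held in at least 1 group for 25 of the 67 genes that could be named in DM against NC, 18 of 61 in AngIV against DM and 15 of 78 in AngIV against NC. The median log2 signal per array was 4.51 ± 0.03 in NC, 4.51 ± 0.01 in DM and 4.50 ± 0.00 in AngIV (log2, mean ± SD, n = 4). The number of arrays limits the precision of the fold changes, whose median standard error was 0.127 on the log2 scale.

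Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, with a mean per group over all 12 arrays, so that the 3 groups shared 1 estimate of the spread. The comparisons were DM against NC, AngIV against DM and AngIV against NC. The labels state no test. Adjusted p-values are Benjamini-Hochberg values over the 13653 genes of a comparison, and a gene was called at an adjusted p under 0.05. Log2 changes are differences of mean log2 signals, given with the standard error (SE) of the fit.

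Gene lists for the heart, diabetes and angiotensin were written before the data were examined, 37 in all, covering metabolism, FoxO and autophagy, protein turnover, matrix, stress and immune pathways, the clock, and markers of cell types that heart tissue can hold. They named 957 genes, of which 860 had a named probe set and 779 were tested. Some lists share members, so their results are not independent. The FoxO list shares Fbxo32, Trim63 and Fbxo30 with the ubiquitin list and Pdk4 with the fatty acid list. With the autophagy list it shares Bnip3, Map1lc3b, Gabarapl1, Atg12 and Ulk2. Each list was tested against all other genes with limma's camera at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 37 lists. Camera with a correlation estimated from the data, and fry, which asks whether the genes of a list move on balance in one direction, were run as alternatives. Members were counted as called over all genes, and again adjusted over the list alone. List symbols were matched through synonyms only where the symbol itself was not current. An earlier matching, which used synonyms more freely and paired 4 listed symbols with other genes, was replaced after its results had been seen, and it is kept as an alternative.

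The genes named in the text follow a rule set before the data were examined. In DM against NC and AngIV against DM it takes the 12 called genes with the largest rise and the 12 with the largest fall whose groups did not overlap on any array, filled up to 12 by smallest p where fewer were called. In AngIV against NC it takes 6 and 6. It adds up to 4 members of smallest p from each list, and 24 genes fixed by interest, among them Foxo1, Foxo3, Map1lc3b, Sqstm1, Fbxo32, Pdk4, Nppa and Col3a1. Lnpep, which was among the 24, is not analysed here, and another of them is not reported here. Unnamed probe sets, RIKEN and Gm genes were replaced by the next named gene. A gene outside the rule is named as such.

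The procedure was tested on simulated data with each gene's mean and spread on the real arrays, 13653 genes and 200 changed genes, in 20 runs per size of change. For DM against NC it recovered 32.2% of 1.41-fold changes, 98.0% of 2-fold changes and 99.8% of 4-fold changes, for AngIV against DM 30.2%, 98.0% and 99.7%, and for AngIV against NC 32.0%, 97.9% and 99.7%. Of the genes it called, 4.51% to 5.84% had not been changed. The shares recovered hold for 200 changed genes of 1 size with independent noise. The adjusted threshold depends on how many genes change, so the shares do not carry over to a comparison with few calls. In DM against NC, Zbtb16 and Ucp3 had log2 changes of 1.57 and 1.48 and were not called. A shift of 0.3 in 1 list of DM against NC was found in 20 of 20 runs, and 1 of 700 unshifted lists was called, in simulations whose genes varied independently of one another.

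Alternatives set before the data were examined covered the replicate number as a block, a fit of only the 2 groups compared, a trend or a robust prior, array weights, quantile normalization again, median centring, other filters on dim genes, other ways to treat several probe sets, other thresholds, other list tests, and leaving out each array in turn. Added after the data had been seen were the mean of the atrial list as a covariate, the separation of control probe sets as a covariate, a filter at the 95th percentile of the negative controls, and the earlier matching of list symbols. Relations between comparisons that share arrays were set beside 100 simulations with no effect and beside values from split arrays. No scan date, array batch or collection time is given in the labels, so none was tested.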

Results

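The series set 3 groups of mouse myocardium side by side to learn how streptozotocin diabetes changes gene expression in the heart and how prolonged angiotensin IV infusion changes it in diabetic mice. The series title names FoxO1-mediated autophagy as the process of interest. There were 12 arrays, with 4 NC, 4 DM and 4 AngIV mice. Correlations between arrays ranged from 0.961 to 0.986 within a group and from 0.962 to 0.984 between groups. The first principal component held 24.1% of the variance. It placed NC at -15.1 ± 2.27, AngIV at 12.9 ± 3.65 and DM between them with a wide spread, at 2.23 ± 12.5 (mean ± SD, n = 4). The 4 DM arrays lay at 16.9, 7.39, -4.12 and -11.3.

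Genes of the atria were unevenly present in the samples. Myl7, the atrial regulatory light chain of myosin, had a log2 signal of 6.49 ± 3.03 in NC, 7.65 ± 2.54 in DM and 3.72 ± 0.20 in AngIV (mean ± SD, n = 4). Myl4, the atrial essential light chain, stood at 7.54 ± 2.0, 7.93 ± 1.63 and 5.53 ± 0.34, and Sln, which encodes the calcium pump regulator sarcolipin, at 6.79 ± 1.97, 7.23 ± 1.53 and 4.99 ± 0.11. Within NC, Myl7 was 10.1 and 7.90 on replicates 1 and 3 and 4.28 and 3.72 on replicates 2 and 4. Within DM it was 8.86, 9.68 and 8.10 on replicates 1, 2 and 4 and 3.97 on replicate 3, while all 4 AngIV arrays lay between 3.53 and 3.94.

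**Figure D1:**
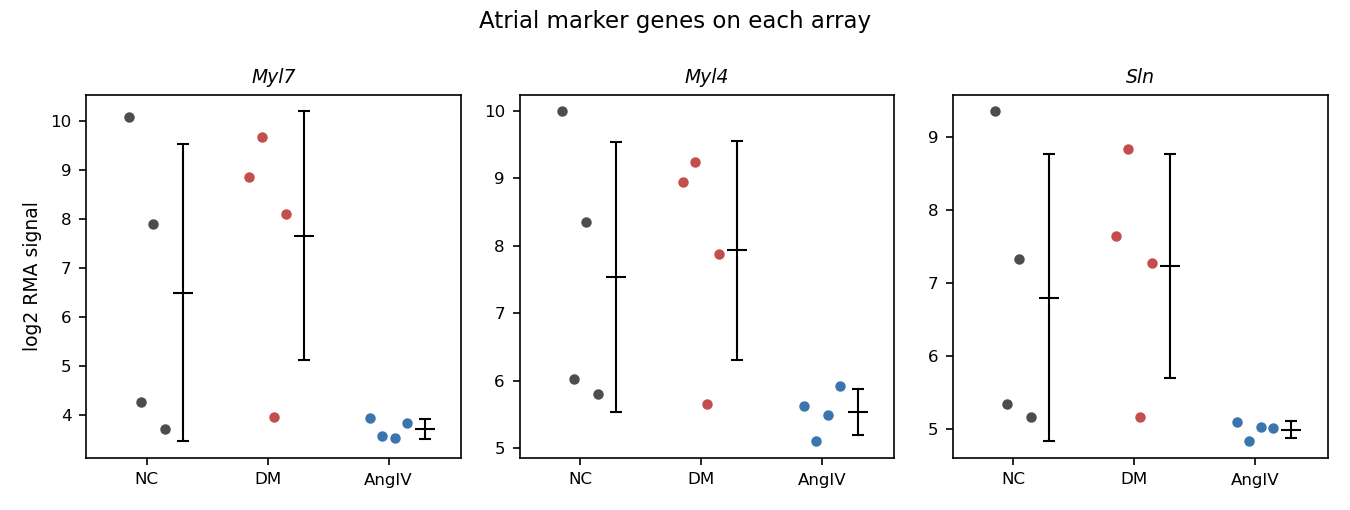
Log2 RMA signal of the atrial genes Myl7, Myl4 and Sln on each of the 12 arrays, by group, with 1 point per array and the group mean ± SD as a bar beside the points. NC and DM each hold arrays with high and low signals of Myl7 (3.72 to 10.1 in NC, 3.97 to 9.68 in DM), while all 4 AngIV arrays lie between 3.53 and 3.94.

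The first comparison, DM against NC, asked what diabetes changed. Arntl, which encodes the core clock activator BMAL1, fell from a log2 signal of 5.78 ± 0.17 in NC to 4.40 ± 0.13 in DM (mean ± SD, n = 4; limma adjusted p = 0.000596). Abat, which encodes the enzyme that breaks down the transmitter GABA, fell from 7.33 ± 0.19 to 5.48 ± 0.39 (limma adjusted p = 0.0031), and Epha4, an ephrin receptor, fell 2.04-fold, from 6.65 ± 0.11 to 5.62 ± 0.17 (limma adjusted p = 0.00716). The DM means of Arntl and Abat lay below 5.53, the 95th percentile of the negative control probe sets on the DM arrays, so no fold is given for them. These were the 3 genes called out of 13653, with 0 genes higher. As groups, genes of fatty acid oxidation, FoxO-regulated genes, interferon and inflammation genes and macrophage markers were higher in DM, and heat shock genes were lower. Camera called 9 lists with its preset correlation and 0 with an estimated one, where the adjusted p of the 9 was 0.452 to 0.582, and fry called 0.

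Fatty acid oxidation and the targets of PPAR-alpha, the nuclear receptor that drives lipid burning, formed the list with the smallest p (camera adjusted p = 4.88e-13, mean log2 change 0.39; adjusted p = 0.582 with an estimated correlation). Of its 35 tested members 32 had a positive change, 0 were called by limma over all genes, 17 were higher at an unadjusted p under 0.05, and 11 were higher and 0 lower when adjusted over the list alone. The acyl-CoA thioesterases Acot1 and Acot2 had log2 changes of 1.61 ± 0.31 (SE) and 1.07 ± 0.24, the rate-limiting carnitine transferase Cpt1a 0.73 ± 0.19 and the triglyceride lipase Pnpla2 0.59 ± 0.13, with limma adjusted p-values from 0.0682 to 0.176. Pdk4, which restrains glucose oxidation, stood at 1.41 ± 0.42, the mitochondrial uncoupling protein gene Ucp3 at 1.48 ± 0.44 and the lipoprotein lipase inhibitor gene Angptl4 at 0.54 ± 0.26, while the glucose transporter gene Slc2a4 had -0.19 ± 0.11. None of these 4 was called.

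The list of FoxO genes and FoxO-regulated genes was higher as a whole (camera adjusted p = 2.53e-06, mean log2 change 0.27; adjusted p = 0.582 with an estimated correlation). Its mean was 7.43, 7.38, 7.06 and 7.07 on DM replicates 1 to 4 and 6.92 to 7.02 on the NC arrays. Of its 32 members 26 had a positive change and 0 were called by limma over all genes, with 14 higher and 1 lower at an unadjusted p under 0.05 and 8 higher and 1 lower when adjusted over the list alone. Pik3ip1, a brake on PI3 kinase, had a log2 change of 1.03 ± 0.21 (SE), the mitophagy receptor gene Bnip3 0.55 ± 0.16, the muscle ubiquitin ligase gene Fbxo32 0.51 ± 0.12 and the cell cycle inhibitor gene Cdkn1b 0.41 ± 0.12. Foxo1 itself was not called, at 5.58 ± 0.15 in NC and 5.72 ± 0.22 in DM (mean ± SD, n = 4), a log2 change of 0.14 with a 95% interval from -0.15 to 0.43 (limma adjusted p = 0.767). Foxo3 had 0.26 ± 0.10 and Foxo4 0.33 ± 0.14, with limma adjusted p-values of 0.375 and 0.406.

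The autophagy list, 40 genes of the machinery that delivers cell contents to lysosomes, was not called (camera adjusted p = 0.27). Of its members 0 were called by limma, and 5 were higher and 0 lower at an unadjusted p under 0.05. Becn1, which starts autophagosome formation, had a log2 change of -0.01 ± 0.09 (SE), the autophagosome marker gene Map1lc3b 0.25 ± 0.11, the cargo receptor gene Sqstm1 0.20 ± 0.11 and Atg7 0.05 ± 0.14. Ubiquitin ligase and proteasome genes were not called either (camera adjusted p = 0.363), and Trim63 among them had 0.15 ± 0.16.

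Immune lists were higher in DM. The interferon list (camera adjusted p = 6.42e-06; adjusted p = 0.582 with an estimated correlation) had 24 of 27 members with a positive change, 8 of them at an unadjusted p under 0.05, such as the antiviral genes Ifit2 at 0.64 ± 0.17 (SE) and Isg15 at 0.42 ± 0.14. The macrophage list (camera adjusted p = 8.72e-06; adjusted p = 0.582 with an estimated correlation) had a positive change in 16 of 16 members, 7 of them at an unadjusted p under 0.05, with Mpeg1 at 1.17 ± 0.39 and the scavenger receptor gene Cd163 at 0.87 ± 0.31. Its mean was 6.63, 6.04, 6.15 and 5.62 on DM replicates 1 to 4 and 5.68 to 5.78 on the NC arrays, so that DM replicate 4 lay below each NC array. The inflammation list (camera adjusted p = 0.000749; adjusted p = 0.452 with an estimated correlation) had 23 of 26 positive, 6 at an unadjusted p under 0.05, among them the chemokine gene Ccl8. On DM replicates 1 to 4 Ccl8 read 7.60, 6.12, 6.41 and 3.14, against 2.93 to 3.98 on the NC arrays, and the mean of the list was 5.53, 5.36, 5.15 and 5.01, against 4.83 to 5.03. The antigen presentation list (camera adjusted p = 0.02; adjusted p = 0.582 with an estimated correlation) had 8 of 10 positive, with the class I genes H2-T23 and H2-D1 at 0.48 ± 0.12 and 0.48 ± 0.13. In each of these 4 lists limma called 0 members over all genes, and adjusted over the list alone 2 members of the antigen presentation list were higher and 0 of the others.

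The circadian list was higher on balance (camera adjusted p = 0.00931; adjusted p = 0.452 with an estimated correlation). Of its 18 members 1 fell, Arntl, and 0 rose over all genes, with 7 higher and 2 lower when adjusted over the list alone. The period genes Per3 and Per2, which repress BMAL1 activity, had log2 changes of 0.82 ± 0.15 (SE) and 0.61 ± 0.13 and the output regulator gene Tef 0.51 ± 0.11, with limma adjusted p-values of 0.0682, 0.0984 and 0.1.

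Heat shock genes, which encode protein-folding chaperones, were lower as a list (camera adjusted p = 0.0013; adjusted p = 0.582 with an estimated correlation), with a negative change in 15 of 18 members. Limma called 0 of them over all genes, 5 were lower at an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone, the cochaperone gene Chordc1 at -0.50 ± 0.14 (SE). The lipogenesis and sterol synthesis list was lower (camera adjusted p = 0.0294; adjusted p = 0.582 with an estimated correlation) with a mean log2 change of -0.09, and its members were mixed, with 0 called by limma over all genes and 1 higher and 5 lower when adjusted over the list alone. Its sterol genes Msmo1 and Cyp51 and the sterol regulator gene Srebf2 had -0.81 ± 0.17, -0.47 ± 0.13 and -0.31 ± 0.09, whereas the desaturase gene Scd4 had 1.71 ± 0.33.

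Among the other fixed genes, none of which was called, the natriuretic peptide genes Nppa and Nppb had log2 changes of -0.39 ± 0.89 (SE) and 0.17 ± 0.42, the myosin heavy chains Myh6 and Myh7 -0.03 ± 0.09 and 0.55 ± 0.28. The collagens Col1a1 and Col3a1 had -0.19 ± 0.16 and -0.45 ± 0.20, Tgfb1 0.13 ± 0.13 and the angiotensin receptor gene Agtr1a 0.16 ± 0.12. The named genes next in line by p, which did not pass, were in order the metallothionein gene Mt2 at 1.49 ± 0.24, Tns2 at 0.60 ± 0.10, Tspan4 at 0.82 ± 0.14, Spon2 at -0.84 ± 0.15 and Slc43a2 at 0.82 ± 0.15. The cholesterol exporter gene Abca1 at 1.22 ± 0.22, the transcription factor gene Zbtb16 at 1.57 ± 0.28, Hsd17b2 at -0.70 ± 0.13 and Prrg4 at 1.03 ± 0.19 followed, all 9 with a limma adjusted p = 0.0682.

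Besides Arntl and Abat, the means of Abca1, Ccl8, Cd163, Per3, Scd4 and Slc43a2 in NC, and those of Cyp51, Foxo4, Hsd17b2, Ifit2, Isg15, Mpeg1, Msmo1, Per2, Prrg4, Spon2 and Tef in both groups, lay below the 95th percentile of the negative controls. In all, 1461 genes had an unadjusted p under 0.05 in DM against NC, 767 higher and 694 lower, where 683 would be expected with no effect. The groups did not overlap on any array for 723 genes, 5.30% of those tested, where chance gives 2.86%. The number of called genes was 30 without DM replicate 4 and 29 with a trend in the prior. The antigen presentation list was not called without DM replicate 3, NC replicate 3 or NC replicate 4 (camera adjusted p = 0.148, 0.0562 and 0.123), nor the lipogenesis list without DM replicate 4, NC replicate 3 or NC replicate 4 (0.194, 0.306 and 0.0679), with a mean change of 0.00 without NC replicate 3. The arrays' means did not overlap between DM and NC for the FoxO and fatty acid lists, 2 of the 9 called, and overlapped for the other 7. The inflammation and lipogenesis lists were not called above the negative controls, a filter chosen after seeing the data (camera adjusted p = 0.0596 and 0.294), nor the lipogenesis list with the dimmest 50% of genes left out (0.23).

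**Figure D2:**
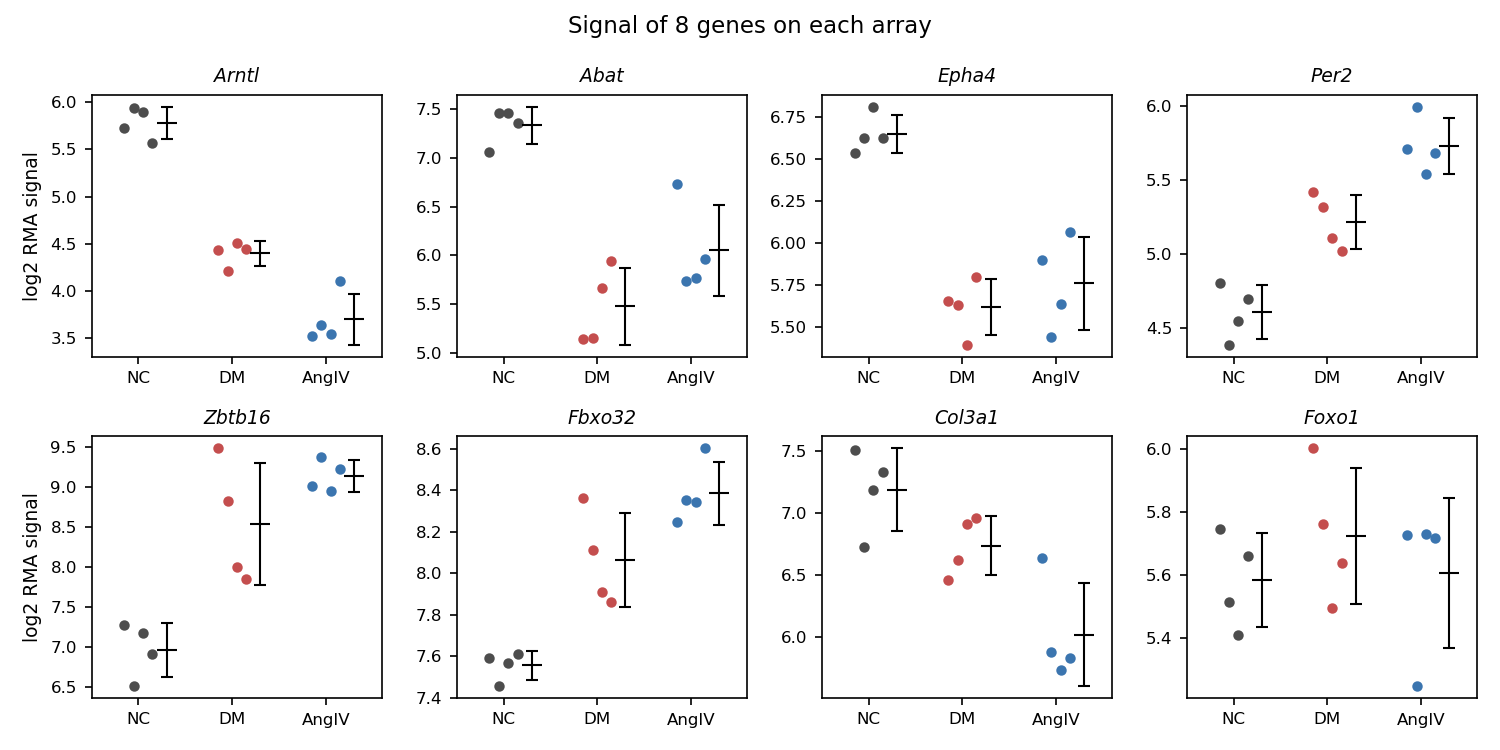
Log2 RMA signal of 8 genes on each of the 12 arrays, by group, with 1 point per array and the group mean ± SD as a bar beside the points; each panel has its own axis range. Arntl, Abat and Epha4 were lower in DM and AngIV than in NC, Per2, Zbtb16 and Fbxo32 were higher and Col3a1 lower in AngIV than in NC, and Foxo1 had means of 5.58, 5.72 and 5.60 in NC, DM and AngIV.

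The second comparison, AngIV against DM, asked what angiotensin IV changed in diabetic mice. Limma called 0 of 13653 genes, with a smallest adjusted p of 0.177, while 1199 genes had an unadjusted p under 0.05. Of 37 lists camera called 8 with its preset correlation, 5 higher and 3 lower, and each of the 8 had an adjusted p = 0.647 with an estimated correlation. Fry called 0 lists. Interferon genes were higher in AngIV than in DM, extracellular matrix genes were lower, and genes of the ubiquitin-proteasome system, autophagy, glycolysis and smooth muscle were higher. Immediate early genes and the atrial markers were lower.

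Interferon response genes (camera adjusted p = 6.72e-05, mean log2 change 0.27; adjusted p = 0.647 with an estimated correlation) had a positive change in 21 of 27 members, and 4 were higher and 0 lower when adjusted over the list alone. They included the immunity-related GTPase genes Igtp, at 5.25 ± 0.27 in DM and 6.49 ± 0.54 in AngIV, and Irgm1, at 6.10 ± 0.15 and 6.95 ± 0.40 (mean ± SD, n = 4). The light chain of class I molecules, B2m, had a log2 change of 0.40 ± 0.11 (SE) and the interferon signal transducer gene Irf9 0.52 ± 0.15. Related GTPase genes outside the list, Irgm2 and Iigp1, stood among the smallest p-values at 1.02 ± 0.19 and 0.96 ± 0.20. The mean of the interferon list was 5.86, 5.24, 5.74 and 5.47 on AngIV replicates 1 to 4 and 5.16 to 5.44 on the DM arrays. AngIV replicate 2 thus lay within the DM range.

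The fibrosis and extracellular matrix list was lower (camera adjusted p = 9.89e-06, mean log2 change -0.20; adjusted p = 0.647 with an estimated correlation), with a negative change in 37 of 45 members. When adjusted over the list alone, 5 were lower and 1 was higher. Collagen III, Col3a1, had 6.73 ± 0.24 in DM and 6.02 ± 0.41 in AngIV (mean ± SD, n = 4), and the lysyl oxidase relative Loxl1 and Col6a1 had log2 changes of -0.53 ± 0.14 (SE) and -0.36 ± 0.10. The receptor gene Tgfbr1, which passes on the matrix-inducing signal of TGF-beta, had 0.48 ± 0.12, Tgfb1 -0.07 ± 0.13 and Col1a1 -0.23 ± 0.16. The atrial and conduction list was lower in the same comparison (camera adjusted p = 0.0218, mean log2 change -0.69; adjusted p = 0.647 with an estimated correlation). The AngIV means of Myl7 and Sln lay below 5.53, the 95th percentile of the negative control probe sets on the AngIV arrays, and that of Myl4 lay at it, so no change is given for them. With the atrial list's mean on each array as a covariate, the mean change of the matrix list was -0.02 and it was no longer called (camera adjusted p = 0.603).

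Ubiquitin ligase and proteasome genes were higher (camera adjusted p = 0.0218, and 0.647 with an estimated correlation), with a positive change in 23 of 27 members. Among them were the muscle ligase genes Trim63 and Fbxo32 at 0.49 ± 0.16 (SE) and 0.32 ± 0.12, both also in the FoxO list. The autophagy list was higher (camera adjusted p = 0.0327, mean log2 change 0.10; adjusted p = 0.647 with an estimated correlation), with 30 of 40 members positive, among them the protease gene Atg4d at 0.31 ± 0.11 and the regulator Ambra1 at 0.28 ± 0.11. Rubcn, known as a negative regulator of autophagosome maturation, had 0.46 ± 0.17, and Map1lc3a -0.28 ± 0.11. The fixed autophagy genes had log2 changes of 0.07 ± 0.09 for Becn1, 0.15 ± 0.11 for Map1lc3b, 0.21 ± 0.11 for Sqstm1, 0.18 ± 0.14 for Atg7 and 0.01 ± 0.16 for Bnip3. Glycolysis and glucose uptake genes were higher (camera adjusted p = 0.0308; adjusted p = 0.647 with an estimated correlation), with 19 of 25 positive, among them the glucose transporter gene Slc2a1 at 0.60 ± 0.17, the hexokinase gene Hk2 at 0.48 ± 0.20 and Gapdh at 0.25 ± 0.10. The aldolase gene Aldoc had -0.36 ± 0.11 and Slc2a4 0.16 ± 0.11. In these 3 lists 0 members passed when adjusted over the list alone, and 5, 6 and 4 were higher at an unadjusted limma p under 0.05. With the atrial covariate none of the 3 was called (camera adjusted p = 0.0745 for the ubiquitin list, 0.112 for autophagy and 0.609 for glycolysis). Their mean log2 changes were 0.11 with it and 0.11 without it for the ubiquitin list, 0.09 and 0.10 for autophagy and 0.05 and 0.12 for glycolysis.

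Immediate early genes, which respond within minutes to stimulation, were lower (camera adjusted p = 0.0222; adjusted p = 0.647 with an estimated correlation), with a negative change in 17 of 24 members, among them Fos at -0.64 ± 0.21 (SE), the phosphatase gene Dusp1 at -0.48 ± 0.14, Btg2 at -0.29 ± 0.15 and Egr2 at -0.26 ± 0.11. Smooth muscle and pericyte markers were higher (camera adjusted p = 0.0369, and 0.647 with an estimated correlation), with 14 of 15 positive. Among them were the pericyte genes Rgs5 at 0.29 ± 0.14 and Notch3 at 0.23 ± 0.14 and the smooth muscle myosin gene Myh11 at 0.56 ± 0.35. Abcc9, which is also in the list of calcium handling, contraction and ion channels, had 0.21 ± 0.10. In the immediate early and smooth muscle lists 0 members passed when adjusted over the list alone. In the direction of the list, 3 immediate early genes and 0 smooth muscle markers reached an unadjusted limma p under 0.05.

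The FoxO list was not called between AngIV and DM (camera adjusted p = 0.149, mean log2 change 0.07). Foxo1 had log2 signals of 5.72 ± 0.22 in DM and 5.60 ± 0.24 in AngIV (mean ± SD, n = 4), a log2 change of -0.12 with a 95% interval from -0.41 to 0.17 (limma adjusted p = 0.818). On AngIV replicate 2 Foxo1 read 5.25 and on the other 3 AngIV arrays 5.72 to 5.73. Foxo3 had a change of 0.29 ± 0.10 (SE) and Foxo4 -0.36 ± 0.14. The fatty acid oxidation list had a mean log2 change of -0.12 and was not called (camera adjusted p = 0.0779), with Pdk4 at -0.81 ± 0.42, Ucp3 at -0.91 ± 0.44 and Angptl4 at -0.20 ± 0.26. Nppa, Nppb, Myh6, Myh7 and Agtr1a had changes of 0.04 ± 0.89, -0.44 ± 0.42, 0.07 ± 0.09, 0.59 ± 0.28 and 0.10 ± 0.12.

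The other genes of smallest p, none of which passed, were Ppm1l at 0.56 ± 0.10 (SE), Lrrc10, a cardiac leucine-rich repeat gene, at 0.70 ± 0.13, Rasl11b at 0.64 ± 0.13, P2ry1 at 0.61 ± 0.13. Lower in AngIV, also without passing, were Gngt2 at -0.59 ± 0.10, Lpcat3, which remodels phospholipids, at -0.74 ± 0.14, Slc41a3 at -0.78 ± 0.17 and Arntl at -0.70 ± 0.13, with both its means below the 95th percentile of the negative controls. Limma adjusted p-values of these 8 genes ran from 0.177 to 0.318. The means of Aldoc, Egr2, Fos, Foxo4, Irf9, Notch3, Ppm1l and Rubcn in both groups, those of Igtp, Myh11, P2ry1 and Tgfbr1 in DM and those of Col6a1 and Gngt2 in AngIV lay below the 95th percentile of the negative controls. Of the 1199 genes with an unadjusted p under 0.05, 720 were higher and 479 lower, where 683 would be expected with no effect. For 787 genes, 5.76%, the groups did not overlap, where chance gives 2.86%. Without AngIV replicate 2 limma called 5 genes and without DM replicate 2 it called 1, and without DM replicate 1 the number of called lists was 3, with the atrial, autophagy, ubiquitin, glycolysis and smooth muscle lists each at a camera adjusted p = 0.0744. Calls were also lost without DM replicate 2 (atrial 0.243, glycolysis 0.117), DM replicate 3 (autophagy 0.0569), DM replicate 4 (autophagy 0.0655, smooth muscle 0.151), AngIV replicate 1 (immediate early 0.144, glycolysis and smooth muscle 0.126), AngIV replicate 3 (smooth muscle 0.0575) and AngIV replicate 4 (autophagy 0.131). Above the negative controls, a filter chosen after seeing the data, the autophagy and smooth muscle lists (0.259 each), the atrial, ubiquitin and immediate early lists (0.0809 each) and the glycolysis list (0.0575) were not called. The autophagy, glycolysis and smooth muscle lists also lost their call with array weights (0.0521 to 0.055) and with quantile normalization again (0.052 to 0.0936), as did the atrial list with the first (0.0518) and the ubiquitin list with the second (0.0745). The arrays' means did not overlap between AngIV and DM for the autophagy list and overlapped for the other 7. The gap of the autophagy list was narrow, with a lowest AngIV mean of 6.574 and a highest DM mean of 6.566. With the dimmest 50% of genes left out the autophagy and smooth muscle lists were not called (0.0865 and 0.0812).

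**Figure D3:**
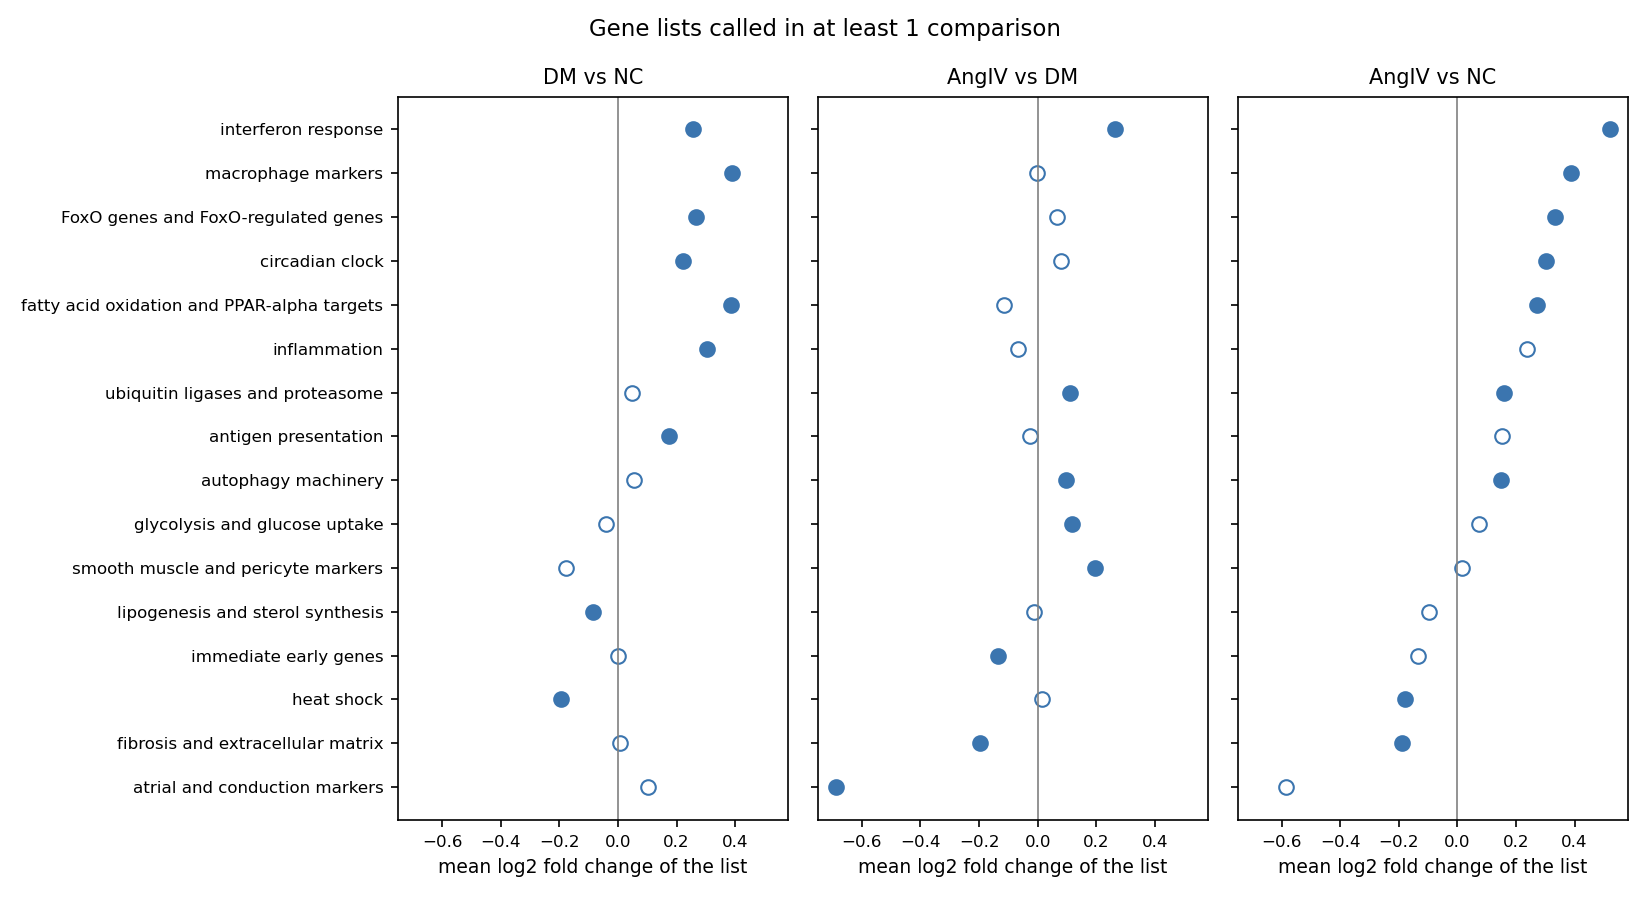
Mean log2 fold change of the members of each gene list called in at least 1 comparison, for DM against NC, AngIV against DM and AngIV against NC. Filled points passed camera with its preset correlation and open points did not; the interferon list stood at 0.26, 0.27 and 0.52 and the fibrosis list at 0.01, -0.20 and -0.19.

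The third comparison, AngIV against NC, set diabetic mice given angiotensin IV against non-diabetic mice, so that it carries diabetes and treatment together. Limma called 293 genes, 208 higher and 85 lower (71.0% higher). Fkbp5, a cochaperone of steroid receptors, rose 5.86-fold, from 5.73 ± 0.62 in NC to 8.28 ± 0.46 in AngIV (log2, mean ± SD, n = 4; limma adjusted p = 0.0157), and Zbtb16 rose 4.51-fold (limma adjusted p = 0.00282). Retnla, a product of alternatively activated macrophages, fell from 6.22 ± 0.73 to 3.71 ± 0.39 (limma adjusted p = 0.00819) and Arntl from 5.78 ± 0.17 to 3.70 ± 0.27 (limma adjusted p = 2.39e-06). Both AngIV means lay below 5.53, the 95th percentile of the negative control probe sets on the AngIV arrays, so no fold is given. Of the 293 genes, 8 belonged to the clock list (6 higher and 2 lower), 8 to the interferon list and 6 to the FoxO list, and among the matrix genes the collagens Col3a1 and Col6a2 fell.

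Cyp1a1, a target of the aryl hydrocarbon receptor, rose with a wide spread in AngIV (2.63 ± 0.47 in NC, 5.73 ± 1.99 in AngIV; log2, mean ± SD, n = 4). The transcription factor gene Etv5 rose from 4.59 ± 0.52 to 6.36 ± 0.16, Fam107a from 4.18 ± 0.49 to 5.67 ± 0.41 and Rasgef1b from 4.71 ± 0.38 to 6.18 ± 0.38. The NC means of these 4 genes lay below 5.48, the 95th percentile of the negative control probe sets on the NC arrays, so no fold is given. The myosin light chain gene Myl1 fell 2.75-fold, Slc41a3 fell 2.72-fold and Abat fell 2.43-fold. Klhdc8a fell from 5.81 ± 0.18 to 4.43 ± 0.49, an AngIV mean below that percentile. Limma adjusted p-values of these genes ran from 0.00106 for Myl1 to 0.0476 for Fam107a. The call of Cyp1a1 was lost without any 1 of the 4 NC arrays and without AngIV replicate 2 or 3 (limma adjusted p from 0.0548 to 0.0741), with a robust prior (0.0946) and with the control separation as a covariate (0.0878). Fam107a lost its call without any 1 of the NC arrays, AngIV replicates 2 to 4 or DM replicate 2 (0.0589 to 0.116), and with a robust prior (0.0853), no filter on dim genes (0.0621) or the control separation (0.132). Fkbp5 was not called without AngIV replicate 4 (0.0502) or NC replicate 2 (0.052), with a robust prior (0.0545) or with the control separation (0.0513).

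Of the 18 clock genes 6 rose, 2 fell and 10 were not called, and 10 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.469 with an estimated correlation). Per3 rose by 1.19 ± 0.15 (log2, SE), Per2 by 1.13 ± 0.13 and the repressor gene Nr1d2 by 0.76 ± 0.11. Arntl and Clock, whose products form the activating pair of the clock, both fell, Clock with a log2 change of -0.66 ± 0.10 (limma adjusted p = 0.00617). Other list tests were run on the clock list as well. It was the only list that fry called in this comparison (fry adjusted p = 0.0332). The clock list was not called above the negative controls, a filter chosen after seeing the data (camera adjusted p = 0.0639). Clock is outside the rule for named genes and was chosen after its values were seen.

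Of the 27 interferon genes 8 rose, 0 fell and 19 were not called by limma, 18 were higher and 0 lower at an unadjusted p under 0.05, and 17 rose when adjusted over the list alone (camera adjusted p = 1.99e-11; adjusted p = 0.645 with an estimated correlation). Ifit2 rose by 1.08 ± 0.17 (log2, SE), Irgm1 by 1.06 ± 0.16, Igtp by 0.98 ± 0.21 and B2m by 0.58 ± 0.11. The call of Igtp was lost without any 1 of the 4 NC arrays and without AngIV replicate 3 or 4 (limma adjusted p from 0.0577 to 0.0772), and that of B2m without AngIV replicate 3 (0.0554). The class I genes H2-K1 and H2-D1 rose by 0.77 ± 0.13 and 0.74 ± 0.13, the 2 called members of the antigen presentation list, which itself was not called (camera adjusted p = 0.196) and whose mean was 0.15 and median -0.00. Macrophage markers were higher as a list (camera adjusted p = 0.00297; adjusted p = 0.687 with an estimated correlation), with 14 of 16 positive, 0 called by limma, 5 at an unadjusted p under 0.05 and 3 higher when adjusted over the list alone. Cd163 stood at 1.18 ± 0.31 and Mpeg1 at 1.43 ± 0.39. The mean of the list was 6.19, 6.35, 6.24 and 5.64 on AngIV replicates 1 to 4 and 5.68 to 5.78 on the NC arrays, so that AngIV replicate 4 lay below each NC array. Mpeg1 read 4.06 there, within its NC range of 3.70 to 4.12. The call of the macrophage list was lost above the negative controls (camera adjusted p = 0.174) and with the control separation as a covariate (0.0548), settings chosen after seeing the data. Its mean log2 change was 0.28 and 0.27 in these, against 0.39 without them.

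Of the 32 FoxO genes and FoxO-regulated genes 6 rose, 0 fell and 26 were not called by limma, with 15 higher and 1 lower at an unadjusted p under 0.05 and 13 higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.72e-06; adjusted p = 0.645 with an estimated correlation). Pik3ip1 rose by 1.28 ± 0.21 (log2, SE), the stress-induced mTORC1 inhibitor gene Sesn1 by 1.15 ± 0.18, Fbxo32 by 0.83 ± 0.12 and Foxo3 by 0.55 ± 0.10. Foxo1 had a log2 change of 0.02 ± 0.14 (limma adjusted p = 0.953) and Foxo4 -0.03 ± 0.14. The autophagy list was higher (camera adjusted p = 0.00369; adjusted p = 0.645 with an estimated correlation), with 1 member that rose over all genes, the receptor gene Calcoco1 at 0.47 ± 0.11, and 8 higher and 0 lower when adjusted over the list alone. Sqstm1, Map1lc3b and Bnip3, with 0.41 ± 0.11, 0.40 ± 0.11 and 0.56 ± 0.16, were among these 8 and had limma adjusted p-values of 0.0657, 0.0728 and 0.0761 over all genes, while Atg7 had 0.24 ± 0.14 and Becn1 0.06 ± 0.09. Ubiquitin ligase and proteasome genes were higher (camera adjusted p = 0.00386; adjusted p = 0.645 with an estimated correlation). Of 27 members 3 rose, Fbxo32, Psmd4 by 0.58 ± 0.14 and Psma6 by 0.40 ± 0.09, with 5 higher and 0 lower when adjusted over the list alone, among them Trim63 at 0.64 ± 0.16. The call of Foxo3 was lost without AngIV replicate 3 (limma adjusted p = 0.0547) or 4 (0.0519). Psma6 was not called without NC replicate 1, 2 or 4 or AngIV replicates 2 to 4 (0.0528 to 0.0943), nor Psmd4 without NC replicate 1 or 2 or any 1 AngIV array (0.0602 to 0.106). Calcoco1 lost its call without any 1 NC or AngIV array or DM replicate 3 (0.0501 to 0.112). Above the negative controls neither the autophagy list (camera adjusted p = 0.0839) nor the ubiquitin list (0.0509) was called.

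Fatty acid oxidation genes were higher (camera adjusted p = 3.69e-05; adjusted p = 0.645 with an estimated correlation). Of 35 members 2 rose, Cpt1a by 0.86 ± 0.19 (log2, SE) and Pnpla2 by 0.75 ± 0.13, with 7 higher and 0 lower when adjusted over the list alone. The coactivator gene Ppargc1a and the dehydrogenase gene Acadl had 0.50 ± 0.13 and 0.38 ± 0.11, and Pdk4, Ucp3 and Angptl4 had 0.60 ± 0.42, 0.58 ± 0.44 and 0.34 ± 0.26. On AngIV replicate 1 the mean of the list was 8.60, within the NC range of 8.44 to 8.68, and on the other 3 AngIV arrays 8.83 to 9.09. Pdk4 and Ucp3 read 7.34 and 5.98 on that array, within their NC ranges of 7.32 to 8.44 and 5.98 to 7.14. Heat shock genes were lower (camera adjusted p = 0.00369; adjusted p = 0.645 with an estimated correlation), with 16 of 18 negative and 1 that fell, the small chaperone gene Hspb1 at -0.37 ± 0.09, while 2 were lower when adjusted over the list alone. The call of Cpt1a was lost without NC replicate 1, 2 or 4 or AngIV replicate 2 or 3 (limma adjusted p from 0.0583 to 0.0939). Hspb1 was not called without NC replicate 1, 2 or 4, DM replicates 2 to 4 or AngIV replicates 2 to 4 (0.0505 to 0.121), nor the heat shock list without NC replicate 4 (camera adjusted p = 0.0617).

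The fibrosis and extracellular matrix list was lower (camera adjusted p = 0.00139; adjusted p = 0.645 with an estimated correlation). Of 45 members 2 fell, Col3a1 by 1.17 ± 0.20 and Col6a2 by 0.63 ± 0.12, 1 rose, the metalloproteinase inhibitor gene Timp3 by 1.09 ± 0.20 (log2, SE), and 42 were not called; adjusted over the list alone 8 were lower and 2 higher. The atrial list had a mean log2 change of -0.59 and was not called (camera adjusted p = 0.066). With the atrial covariate the mean change of the matrix list was -0.04 and it was not called (camera adjusted p = 0.466), whereas Col3a1 had -1.17 and Col6a2 -0.66. Both were called, with limma adjusted p-values of 0.0203 and 0.0204. Igtp, Calcoco1, Cpt1a and Hspb1 were not called with that covariate (limma adjusted p = 0.0547, 0.0513, 0.0579 and 0.0677). Their log2 changes in that fit were 0.94 ± 0.24 (SE), 0.51 ± 0.13, 0.84 ± 0.22 and -0.38 ± 0.10. These changes were 0.963 to 1.07 times those without the covariate, and their standard errors 1.14 to 1.15 times. Without NC replicate 1 the list had a mean of -0.07 and was not called (camera adjusted p = 0.189), and Timp3 was not called without NC replicate 2 (limma adjusted p = 0.0508). Col1a1 had -0.42 ± 0.16, Tgfb1 0.06 ± 0.13, Nppa -0.35 ± 0.89, Nppb -0.27 ± 0.42, Myh6 0.04 ± 0.09, Myh7 1.14 ± 0.28, Slc2a4 -0.03 ± 0.11 and Agtr1a 0.27 ± 0.12, and none of these 8 was called. The 95% interval of Myh7 ran from 0.53 to 1.74. Adjusted over the cardiac stress list alone, Myh7 was higher, the only member that passed there.

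In AngIV against NC 2542 genes had an unadjusted p under 0.05, 1485 higher and 1057 lower. The groups did not overlap for 1742 genes, 12.8% of those tested, where chance gives 2.86%. The number of called genes was 163, 105 and 185 without NC replicates 1, 2 and 4, 469 without DM replicate 1, and 154, 106 and 104 without AngIV replicates 2, 3 and 4, and 45 of the 293 changed at least 2-fold. The means of Cd163, Per2 and Per3 in NC and those of Foxo4, Ifit2 and Mpeg1 in both groups also lay below the 95th percentile of the negative controls. The arrays' means did not overlap between AngIV and NC for 5 of the 9 called lists, FoxO, autophagy, ubiquitin, circadian and interferon. Some of these gaps were narrow. The lowest AngIV and highest NC means were 5.242 and 5.232 for interferon, 7.979 and 7.97 for ubiquitin and 6.574 and 6.552 for autophagy. With the control separation as a covariate the calls of B2m, Igtp, Calcoco1, Cpt1a, Hspb1, Psma6 and Psmd4 were lost (limma adjusted p from 0.0504 to 0.116). Their log2 changes in that fit were 0.53 ± 0.11 (SE), 1.03 ± 0.23, 0.41 ± 0.11, 0.81 ± 0.21, -0.38 ± 0.10, 0.41 ± 0.10 and 0.57 ± 0.15. Over the 21 named genes that lost their call with it, Fkbp5, Cyp1a1 and Fam107a included, the changes were 0.849 to 1.05 times those without it and the standard errors 1 to 1.12 times. Calcoco1, Hspb1, Psma6 and Psmd4 were also not called with no filter on dim genes (0.0621 to 0.0798). The same held for Calcoco1 with quantile normalization again (0.0505), and for Hspb1 with median centring (0.0545) or only the 2 groups compared (0.0634).

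Both contrasts of the treatment question share the DM arrays, which alone sets their fold changes against each other. The slope of the AngIV minus DM change on the DM minus NC change was -0.124 over all genes, where simulations with no effect gave -0.501, and the covariance was -0.00505 against a simulated -0.0108. With the 4 DM arrays split so that different arrays served the 2 sides, the mean slope over the 6 ways was 0.105, ranging from -0.0621 to 0.332, the last with DM replicates 1 and 2 on the NC side. Of the 3 genes called in DM, Abat and Epha4 had an AngIV minus DM change of opposite sign and Arntl one of the same sign, and 0 of the 3 were called in AngIV against DM.

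The changes of DM against NC and of AngIV against NC had a correlation of 0.701 across genes, which are not independent replicates, where shared NC arrays alone gave 0.5. The covariance was 0.0358 against a simulated 0.0108, and with the NC arrays split the correlation averaged 0.303 (0.0917 to 0.405) and the covariance 0.0197. Arntl, Abat and Epha4 were called lower in both comparisons and 0 genes higher in both. Unchanged groups simulated against common NC arrays shared 0 calls in 100 runs, which leaves out the effects. Independent lists of these sizes would share 0.0187 lower calls, which leaves out the common NC arrays. With the NC arrays split, so that 2 served each comparison, the shared lower calls averaged 1.33 over the 6 ways (1 to 3).

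Of the 37 lists, 21 were called in no comparison, with camera adjusted p-values from 0.059 to 0.997. The renin-angiotensin list had adjusted p-values of at least 0.91 in all 3 comparisons. Of its 20 genes 13 were tested, and Lnpep was not among them. The smallest adjusted p of a list was 0.059 for ketone body metabolism, 0.0637 for oxidative phosphorylation and 0.15 for cardiac stress genes and for lysosome, all in AngIV against NC. It was 0.107 for the tricarboxylic acid cycle, 0.718 for glycogen and hexosamine metabolism, 0.44 for calcium handling, contraction and ion channels, 0.357 for lymphocyte and neutrophil markers and 0.591 for nerve and glia markers, in DM against NC. In AngIV against DM it was 0.0729 for fibroblast markers, 0.0835 for insulin and IGF signalling, 0.109 for epicardial and 0.13 for blood cell markers. In AngIV against NC it was 0.196 for endothelial and for skeletal muscle markers, 0.341 for oxidative stress defence, 0.353 for the cell cycle, 0.63 for endoplasmic reticulum stress and for adipocyte markers, and 0.797 for apoptosis. Mean, median and test differed in sign in 17 of the 111 list results, of which 0 were called.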

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

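The covariate tests of the AngIV against NC genes and the glucocorticoid list were added after the data had been seen, and of the tests only that on the time of collection was written after its result was known.

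The 293 genes called in AngIV against NC were weighed against atrial tissue in the samples, since Myl7 was lower in all 4 AngIV arrays than in the high NC and DM arrays, and against array signal over background. With the mean of the atrial list as a covariate, the log2 fold changes of the 293 genes kept a median of 1.08 of their size (quartiles 1.01 and 1.14), and 374 genes were called, 232 of them among the 293. With the separation of control probe sets as a covariate the median ratio was 0.956 (quartiles 0.895 and 1.01), all 293 genes kept their sign, and 109 genes were called, 105 of them shared, while the median standard error went from 0.134 to 0.139. For these 293 genes neither covariate took away most of the change at the median. Their selection made such a loss unlikely in advance, so the tests do not decide on either cause. The genes were chosen by their call, which a gene with a wide spread within a group seldom gets, and atrial genes spread widely within NC and DM. Genes that were not called are therefore not covered, and the matrix list, tested whole, lost its call with the atrial covariate. Diabetes and angiotensin IV, which this comparison does not separate, stay open. In DM, 290 of the 293 genes had a change from NC of the same sign. The median share of the AngIV minus NC change reached in DM was 0.55. Both comparisons share the NC arrays, which pushes these values up.

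Whether chance could part the arrays as well was tested by refitting all 35 ways to part the 8 arrays of a comparison 4 and 4. For the genes of AngIV against NC 1 of 35 splits, the real one, was as large (293 genes, highest other split 0). That is the smallest share that 35 splits can give, and several such tests were run. It argues against chance and does not exclude it, since a mixed split also holds any group difference in its spread. For the genes of DM against NC chance cannot be excluded, with 2 of 35 splits as large (3 genes, highest other 3). For AngIV against DM the count says nothing about chance: the real split called 0 genes, so 35 of 35 splits were as large by construction (highest other 0). For the lists chance cannot be excluded either. As large were 10 splits in DM against NC (9 lists, highest other 15) and 11 in AngIV against DM (8 lists, highest other 12). In AngIV against NC 10 were as large (9 lists, highest other 12).

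Of the 8 clock genes called in AngIV against NC, 6 rose and 2 fell. Normalization was weighed first: 7 of the 8 passed both with quantile normalization again and with median centring. Both rescale values that RMA had already quantile normalized, and the raw arrays were not processed again. The result therefore argues only against a remaining difference in scale between arrays, and it cannot decide on the first normalization. A difference in the time of day of collection may give the same picture, since the 6 that rose and the 2 that fell belong to opposite arms of the clock. It cannot be told apart from an effect of diabetes or treatment on the clock, because the labels give no collection time. The 2 arms describe the 8 called genes only. Nr1d1 was also lower when adjusted over the list alone, at -0.54 ± 0.24 (log2, SE), whereas Nr1d2 rose. Over all genes Nr1d1 was not called (limma adjusted p = 0.233). Nr1d1 is outside the rule for named genes and was chosen after its values were seen.

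Fkbp5 and Zbtb16, which respond to glucocorticoid hormones, rose in AngIV against NC, and glucocorticoid exposure is a candidate explanation. A list of 10 other responsive genes, 9 of them tested, had a mean log2 0.317 higher in AngIV than in NC (exact two-sided permutation test, p = 0.0857), with 6 of 9 positive and 1 called, Sult1a1 at 1.22 (limma adjusted p = 0.0351), which was chosen after its values were seen. The difference passed the size set in advance and not the p, so it stays undecided; in DM against NC it was 0.244 (exact p = 0.143) and in AngIV against DM 0.073 (exact p = 0.686). Array signal was weighed too: with the control separation as a covariate the fold changes of Fkbp5, Zbtb16 and Tsc22d3 kept a median of 0.899 of their size. Fkbp5 lost its call in that fit (limma adjusted p = 0.0513), and Tsc22d3 was not called without the covariate (0.141). The mean separation was close in both groups, 0.924 ± 0.004 in NC and 0.920 ± 0.004 in AngIV (mean ± SD, n = 4). Fkbp5 and Zbtb16 were chosen for their rise. A large loss was thus unlikely in advance, and the test does not decide on array signal. Tsc22d3 is outside the rule for named genes and was chosen after its values were seen.

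Single arrays stood far from the other 3 of their group in 22 of 540 groups of values tested, 4.07%, where chance gives about 5%. Low values were Isg15 at 3.42 (others 3.89 to 3.93), Egr2 at 4.86 (5.12 to 5.17) and the mean of the lysosome list at 6.49 (6.65 to 6.67) on AngIV replicate 4. On AngIV replicate 2 Psmb9 at 5.38 (5.68 to 5.71) and Foxo1 at 5.25 (5.72 to 5.73) were low. Lpcat3 was low on AngIV replicate 1 at 7.67 (8.10 to 8.16), where Col3a1 was high at 6.63 (5.73 to 5.88) and the mean of the ketone body list at 8.29 (7.78 to 7.83). High values were Ppargc1a at 9.75 (9.34 to 9.40) on AngIV replicate 4, and Dusp1 at 7.93 (7.37 to 7.46) and the mean of the apoptosis list at 6.01 (5.92 to 5.93) on AngIV replicate 2. On NC replicate 2, Sqstm1 was low at 9.09 (9.28 to 9.30), Loxl1 at 6.02 (6.18 to 6.20) and the mean of the adipocyte list at 4.28 (5.21 to 5.4), and Mt1 was high at 9.87 (9.69 to 9.72). On DM arrays, Myh6 was low at 11.7 (others 11.9) and the mean of the ubiquitin list high at 7.99 (7.89 to 7.90) on replicate 2. DM replicate 1 had Iigp1 low at 5.81 (6.14 to 6.18) and Irf9 high at 4.95 (4.59 to 4.61). DM replicate 3 had Btg2 high at 6.32 (5.80 to 5.87), and DM replicate 4 had Notch3 low at 4.94 (5.29 to 5.34) and Myh11 low at 4.85 (5.30 to 5.37).

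Probe sets that carry no gene name were tested apart from the named genes, 1523 of them after the same filter. Limma called 2 in AngIV against DM, both lower (139 at an unadjusted p under 0.05), 20 in AngIV against NC, 16 higher and 4 lower (281 unadjusted), and 0 in DM against NC (140 unadjusted).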

How the results depend on the processing

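The covariates, the filter at the negative controls and the looser symbol matching were chosen after seeing the data; the other settings were set before the data were examined. Of the genes called in DM against NC, Abat and Epha4 kept their call under the 26 alternatives run and Arntl under 25, since its mean lay below the filter at the negative controls. Foxo1 was called under none of 26 (log2 change 0.05 to 0.22 in DM against NC, adjusted p 0.632 to 0.959; -0.20 to -0.00 in AngIV against DM, 0.723 to 1). Of 49 named genes called in AngIV against NC 23 kept their call in each setting they were tested under and 26 lost it in some. Of 26 list calls 10 were kept in every alternative run for them but the other list tests, 16 were lost in some and 0 reversed. With an estimated correlation 0, 0 and 0 lists were called in DM against NC, AngIV against DM and AngIV against NC. Fry called 0, 0 and 1, the circadian list. The mixed form of fry asks whether members change in either direction and does not set them against other genes. It called 9, 3 and 25 lists. At an unadjusted p with at least 1.5-fold, 153 genes passed in DM against NC and 61 in AngIV against DM, and 45 in AngIV against NC at an adjusted p with at least 2-fold. Gene counts in DM against NC and AngIV against NC were 5 and 466 with only the 2 groups compared, 29 and 576 with a trend in the prior, 20 and 504 with the dimmest 50% left out (fewer genes tested), 24 and 594 above the negative controls, and 15 and 109 with the control separation as a covariate. With the atrial covariate DM against NC had 5. Lists in AngIV against DM numbered 4 with array weights, 5 with quantile normalization again, 4 with the atrial covariate, 13 with the control separation and 3 above the negative controls. With the replicate number as a block 3, 0 and 218 genes and 9, 8 and 10 lists were called, and Cyp1a1, Fam107a, Calcoco1, Hspb1, Psma6, Psmd4, Atp5d, Eif4ebp1, Fabp4 and Pygb were not called in AngIV against NC (adjusted p 0.0558 to 0.0859); only 2 of 12 same-numbered pairs had a correlation over 0.1 and 2 of 12 arrays were closest to their own number, so the numbers were not read as a pairing. Leaving out 1 array at a time gave 3 to 30 genes in DM against NC (10 without NC replicate 1, 5 without NC replicate 2, 9 without DM replicate 3, 30 without DM replicate 4), 0 to 5 in AngIV against DM (5 without AngIV replicate 2, 1 without DM replicate 2) and 104 to 469 in AngIV against NC. It gave 3 to 11 lists in AngIV against DM and 9 to 14 in AngIV against NC (14 without NC replicate 2 or AngIV replicate 4). The slope was -0.124 with all 4 DM arrays on both sides, which share their errors. The DM genes opposite in sign under AngIV were 2 of the 3 called in the fit reported. With split arrays they averaged 4.5, mostly from 1 split with 25 of 176 called genes, while the other splits called at most 2. Leaving out the dimmest 50% gave 11 of 20. Without 1 array they ran from 2 to 18. These were 6 of 10 without NC replicate 1, 6 of 9 without DM replicate 3, 4 of 5 without NC replicate 2 and 18 of 30 without DM replicate 4. With looser symbol matching 8, 8 and 9 lists were called, and the lipogenesis list in DM against NC was not (adjusted p = 0.105). The robust prior and every probe set were not run for lists. Where no construction is named, the cause was not tested. Signal over background limits dim genes, which arrays compress.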

Other observations

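Genes of lists that were not called in AngIV against NC also rose or fell one by one there, and all 15 named here follow the rule for list members. The survival factor gene Bcl2l1 rose by 1.27 on the log2 scale and the endoplasmic reticulum protein gene Herpud1 by 1.09. The metal-binding metallothionein genes Mt2 and Mt1 rose by 1.21 and 0.70, the insulin signalling subunit gene Pik3r1 by 0.87 and the lipid droplet gene Plin4 by 0.80. The translation repressor gene Eif4ebp1, also in the FoxO list, rose by 0.79, Ier3 by 0.74, the glycolysis regulator gene Pfkfb3 by 0.57 (both means below the 95th percentile of the negative controls), the glycogen genes Ppp1r3a and Pygb by 0.47 and 0.42 and the fatty acid carrier gene Fabp4 by 0.40. Dusp1 had a log2 change of -0.71, and the ATP synthase genes Atp5g1 and Atp5d had -0.45 and -0.44. Limma adjusted p-values ran from 0.00617 for Herpud1 to 0.0379 for Pygb. Herpud1 kept its call without each array in turn, and each of the others lost it without at least 1 array (adjusted p from 0.0518 to 0.11).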
